A study of Mus musculus with 12 samples.

How the data were processed

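RNA bound by Flag-tagged Puf60 with exon 5, Puf60 without exon 5 or Rbm38 was isolated from N2A cells by iCLIP with an anti-Flag antibody, in 3 CLIP libraries and 1 size-matched input per protein, per the labels' protocols. Partial RNase digestion, size selection on a gel and membrane, and reverse transcription with primers that carry random bases preceded sequencing, per the labels' protocols. Nothing in the labels says whether the replicates came from separate cultures. The submitters' processing notes name TopHat and edgeR, without versions, and the genome builds NCBIM37 and mm10, with no role given for any. Whether reads were collapsed by the random bases, how clusters were called, and how the replicates and the input entered the comparison are not given in the sources used here.

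The authors deposited 1 table per protein, with a cluster's chromosome, start and end and their own comparison of CLIP with input. The deposited log2 fold change was read as a log2 value of CLIP over size-matched input, a direction that the column name alone does not give. The deposited p-value and adjusted p-value stand beside it, per the file headers. The p-value behaves as one-sided: it was under 0.5 at 98.2%, 97.8% and 98.4% of clusters with a log2 fold above 0 and at 0% of those below 0. It is missing at 144, 157 and 264 clusters, and written as 0 at 366, 370 and 986. Many clusters share 1 pair of log2 fold and p-value (at most 245, 216 and 100), so whether the p-value includes the spread between replicates is unknown. The tables hold 0 further columns of values. Totals per library were not used here, so depth is unknown. Read numbers per cluster are not given, and how the p-value depends on them is not stated.

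The planned tests on counts or normalized values per library were not made, since the tables hold comparisons only; the authors' columns are described instead. A cluster was called enriched at a deposited adjusted p under 0.05. Depletion and the alternative adjustment were computed from the deposited p-value by Benjamini-Hochberg.

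Cluster starts fall on a grid of 50 nt with an offset of 0 or 35, which was read as the strand. In protein-coding genes that hold at least 5 enriched clusters and overlap no other gene at them, 99.1%, 99.0% and 98.5% of enriched clusters had the gene's main offset, against 62.0%, 62.0% and 61.4% with random offsets. Neighbouring clusters that overlap (641, 692 and 973 pairs) had different offsets in every case. The offset of 0 covered 100% of the mitochondrial ribosomal RNA genes and was taken as the plus strand. The strand is thus inferred, not stated. Coordinates are printed 1-based on mm10: of the cluster centres, 658, 687 and 562 lay in tRNA, snoRNA or snRNA genes of GRCm38.p6, the same build, against 8, 11 and 10 after a shift of 10000 nt.

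A cluster was given to the gene whose body holds its centre, using 49976 genes with coordinates. Where several did, the gene whose inferred strand matched was taken if it was the only one; the others were left as several genes. A gene's strand was inferred where at least 3 clusters lay in it alone and 80% or more shared an offset, which gave 5194 genes. The reference used here gives gene bodies without exons or sequence, so the planned split into exons, introns and untranslated regions, motif content and distance to splice sites were not run.

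Overlap needed at least 1 nt on the same strand. Its comparison level came from 100 moves of each cluster to a random grid position in the same gene, whatever the read coverage there. Clusters of a pair of tables were matched where each was the other's largest overlap. Target genes and gene lists were tested with two-sided Fisher's exact tests against the 9737 genes listed in any table, with Benjamini-Hochberg adjustment over 3 pairs or over the 11 lists per protein. The fixed rule for genes named in the text takes the 10 clusters of highest log2 fold per table among those past the threshold, 1 per gene, up to 4 members of each list by smallest p-value (ties by log2 fold), Puf60 and Rbm38, and the 10 largest differences in each direction between the isoforms. Predicted genes, genes named only by a clone or locus number, and pseudogenes were left out, so the highest log2 fold of a table and the widest differences between the isoforms need not be among those named. Some genes that the rule names are not reported here. After the data were examined, clusters on the strand opposite to their gene's inferred strand were left out of that ranking as well, and the isoform differences were ranked by size among matched clusters enriched in at least 1 table, since no test was possible. Genes without an inferred strand, such as Nfia, Ank2, Mphosph8 and Malat1, stayed in, so antisense clusters could not be left out there.

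Tests fixed before the data were examined cover enriched clusters, overlap, target genes, regions and gene lists; the versions of the cluster overlap between proteins, target gene overlap and regions restricted to enriched clusters, the position along genes, the small RNA classes and the chromosome comparison were added after. Alternatives were a threshold of 0.01, an overlap of 50% of both clusters, either strand, the more strongly enriched 50% of clusters, at least 2 clusters per gene, all protein-coding genes as background, gene length as a covariate, and the added ones named in the closing section. The more strongly enriched 50% of each table was taken by deposited p-value, with ties by log2 fold. The overlap, matching and strand steps were tested on simulated clusters spread evenly along the real genes, and the gene list test on simulated counts alone. With 30% of 9924 clusters planted as shared, 31.0% overlapped and 1.52% did after random moves; with none planted, 1.50% and 1.42% of 9930 did. Of 9670 planted pairs, 99.4% were matched. Planted gene lists were called in 100% of cases and unchanged lists in 1.43%, with counts drawn at random for 9600 genes. This did not test the assignment of clusters to genes. Inferred strands were right for 100% of 1362 genes. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.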

Results

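Crosslinking and immunoprecipitation with sequencing (iCLIP) was used to map where 3 Flag-tagged RNA-binding proteins contact RNA in N2A cells, a mouse neuroblastoma line. The proteins were Puf60 with its exon 5, Puf60 without exon 5, and Rbm38. Puf60 is a splicing factor related to U2af2 that binds pyrimidine tracts near 3′ splice sites, and Rbm38 is an RNA-binding protein encoded by a p53 target gene. Each protein was expressed from a doxycycline-inducible transgene (1 µg/ml) and had 3 CLIP libraries and 1 size-matched input, RNA of the same size range taken without the immunoprecipitation, which makes 12 samples. Cells received 150 mJ/cm2 of ultraviolet light. Per the labels, the 3 libraries of Puf60 with exon 5 were induced for 48 h, and all other libraries, including the input of that line, for 24 h. The fold over input of Puf60 with exon 5 thus also sets 48 h of induction against 24 h. Isoform and induction time therefore cannot be told apart in any comparison of the Puf60 tables.

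The values used here are the authors' own: per protein, a table of genomic clusters with a log2 fold of CLIP over input, a p-value and an adjusted p-value. They hold no values per library, so the spread between replicates and the depth of each library are unknown, and no test across replicates was possible. The tests below compare sets of clusters or genes. They and the 95% Wilson intervals cover counting error only, and clusters are not independent replicates.

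The transcripts of the tagged genes were examined first. Rbm38 (gene 56190, chromosome 2, 173021891 to 173034734) had 5 clusters in the Rbm38 table and none in either Puf60 table. Of these, 4 were enriched over input, with log2 folds of 3.35, 1.63, 2.41 and 2.73 in the authors' deposited table. Puf60 (gene 67959, chromosome 15, 76070182 to 76082537) had 15 clusters, 12 of them enriched, in the table of Puf60 with exon 5, and 13 clusters, 7 enriched, in the table without exon 5. The strongest lay at 76079536 to 76079585 in both, with log2 folds of 4.88 with exon 5 and 4.79 without exon 5 in the authors' deposited tables. The Rbm38 table listed 2 clusters in Puf60, of which the enriched one, at 76070236 to 76070335, had a log2 fold of 4.43 in the authors' deposited table. At the same place both Puf60 tables held a cluster that was not enriched, at -0.45 with exon 5 and -0.39 without it, as the authors' deposited tables give them. Reads of the transgene and of the endogenous gene cannot be separated in these clusters.

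The first question of the design is which RNAs each protein contacts above input. Puf60 with exon 5 had 14182 enriched clusters among 36227 (39.1%, 38.6 to 39.7) at the authors' adjusted p of 0.05, in 4269 genes. Puf60 without exon 5 had 14235 among 39454 (36.1%, 35.6 to 36.6), in 4240 genes, and Rbm38 had 25063 among 49260 (50.9%, 50.4 to 51.3), in 6079 genes. The median log2 fold of enriched clusters was 2.89 (quartiles 1.66 and 3.66), 2.80 (1.47 and 3.68) and 2.33 (1.65 and 3.04), from the authors' deposited tables. A stated p-value under 0.05 did not always bring a low adjusted p. It stood beside an adjusted p of 1 at 1806, 1684 and 5767 clusters, by a criterion not given in the sources used here.

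Among the enriched clusters of named genes that the ranking kept, which leaves out predicted and numbered genes, the highest log2 folds for Puf60 with exon 5 in the authors' deposited table were at Ppp1r12a (7.47, chromosome 10, 108162201 to 108162300), which encodes a myosin phosphatase subunit, and Fubp1 (7.24, chromosome 3, 152227351 to 152227550), which encodes a nucleic acid-binding protein. Taok3 (7.16), Six2 (6.92), Mast2 (6.90), Efna5 (6.89), Srd5a3 (6.81), Rspo3 (6.81), Cnot2 (6.75) and Top2b (6.73) followed in the authors' deposited table. Six2 encodes a homeobox transcription factor, Efna5 an axon guidance ligand, Cnot2 a subunit of the CCR4-NOT deadenylase and Top2b a DNA topoisomerase. For Puf60 without exon 5, the highest by the same rule in the authors' deposited table were Aldh5a1 (7.45, chromosome 13, 24913551 to 24913700), Nfat5 (7.39, chromosome 8, 107374501 to 107374800) and Fubp1 (7.28, chromosome 3, 152227251 to 152227500). Shc4 (7.25), Mast2 (7.22), Cacng3 (7.17), Stxbp6 (7.07), Slc38a1 (7.06) and Agap1 (6.99) were also among the highest in the authors' deposited table. The clusters of Fubp1 overlapped between the isoforms, and that of Mast2 spanned chromosome 4, 116330436 to 116330635, in both of the authors' deposited tables. By this rule Rbm38 had its highest log2 folds in the authors' deposited table at Rps24 (6.65, chromosome 14, 24495751 to 24495850), a ribosomal protein gene, Grn (6.50, chromosome 11, 102436651 to 102436800), which encodes progranulin, and Ap2s1 (6.49), an endocytic adaptor gene. Mapt, which encodes the microtubule-binding protein tau (6.43, chromosome 11, 104330001 to 104330100), Sec61g (6.40), Nlgn1 (6.36), Dnmt1 (6.33), Atp6ap2 (6.32), Cep290 (6.19) and Ephb1 (6.18) came next in the authors' deposited table. Measured to the gene's 3′ end on the strand inferred from the clusters, the cluster centres of Grn, Sec61g, Dnmt1, Atp6ap2, Rps24, Mapt and Cep290 lay 84, 123, 155, 501, 1160, 2040 and 8446 nt away, taken from the positions in the authors' deposited table. For Ap2s1, Nlgn1 and Ephb1 the clusters gave no strand, nor did they for Taok3, Six2, Srd5a3 and Rspo3 above. Whether the clusters named at these genes are sense or antisense is thus unknown.

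Enriched clusters were often crowded in the same genes. For Puf60 with exon 5, Pcbp3 held 92 of 391 listed clusters, Huwe1 75 of 123, Cpsf6 56 of 63, Pcm1 49 of 64 and Rbm26 45 of 49. Without exon 5, Huwe1 held 87 of 134, Pcbp3 56 of 236, Fubp1 49 of 65, Pcm1 47 of 62 and Cpsf6 45 of 59. For Rbm38 the leading genes were Pcbp3 with 296 of 640, Maml3 with 169 of 362, Samd5 with 145 of 558, Map1b with 142 of 278 and Ankrd11 with 129 of 199. Over whole tables the enriched shares were 39.1%, 36.1% and 50.9%. Pcbp3 lay below this share in each table, as did Maml3 and Samd5 for Rbm38, and the other genes named lay above it. Pcbp3 encodes a poly(C)-binding protein, Huwe1 a ubiquitin ligase, Cpsf6 a 3′ end processing factor and Map1b a microtubule-associated protein. These counts follow how the authors divided each gene into clusters and how much RNA the gene yields, which was not used here.

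The Puf60 isoforms are the direct comparison of the design. Clusters matched between their tables carried nearly the same enrichment over input, and 27.7% and 30.5% of the enriched clusters with and without exon 5 had no counterpart. Of the 14182 enriched clusters with exon 5, 9101 (64.2%) overlapped an enriched cluster without exon 5, 1150 (8.11%) overlapped only a cluster that was not enriched, and 3931 (27.7%) met no listed cluster. In the opposite direction the shares were 63.7%, 5.75% and 30.5% of 14235. Clusters without a counterpart were also well above input, with median log2 folds of 2.78 with exon 5 and 2.40 without, against 3.18 and 3.13 for those that overlapped an enriched cluster, from the authors' deposited tables. Matching clusters between the tables by largest mutual overlap gave 20187 pairs. Across these pairs the log2 folds had a Pearson r of 0.943 (95% interval 0.941 to 0.944) and a Spearman rho of 0.920, over clusters, which are not independent replicates. The median of log2 fold with exon 5 minus without was 0.10, with an SD over pairs of 0.71. Enrichment in both tables was found at 8822 pairs, with exon 5 alone at 1106, without exon 5 alone at 850 and in neither at 9409, an odds ratio of 88.3 (p = 0 at machine precision, two-sided Fisher's exact test).

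**Figure D1:**
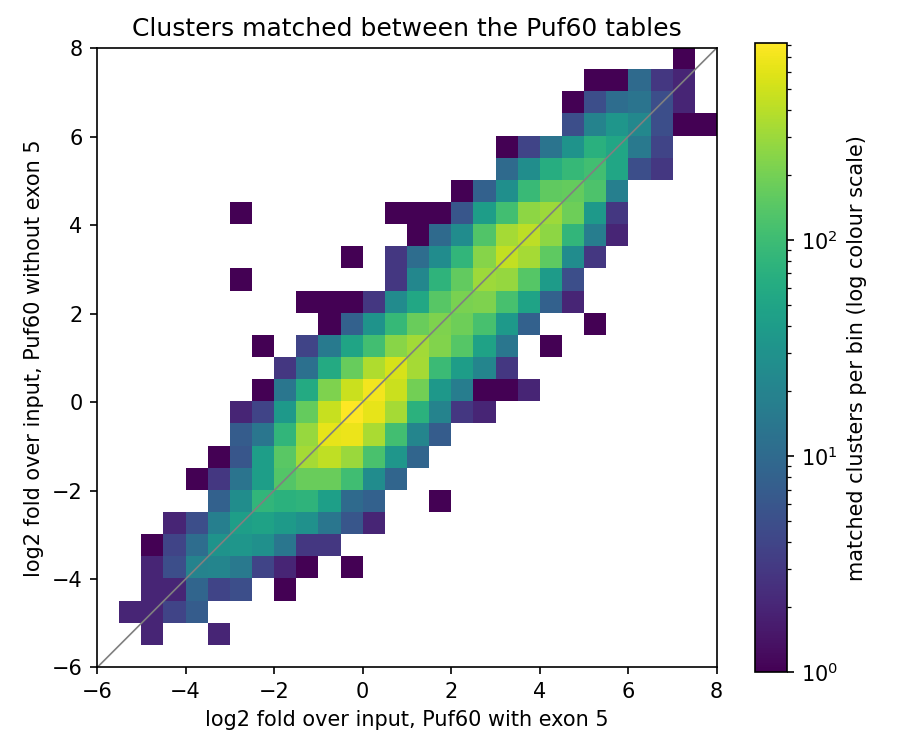
Log2 fold over input of 20187 clusters matched between the Puf60 tables, with exon 5 on the x axis and without exon 5 on the y axis, as the authors' deposited tables give them; colour shows the number of matched clusters per bin on a log scale, and the grey line marks equal values. The pairs lie along the line, with a Pearson r of 0.943.

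Few pairs differed widely. Among the 10778 pairs enriched in at least 1 table, 92 had a log2 fold more than 2 higher with exon 5 and 36 more than 2 lower. The differences of pairs enriched in neither table lay between -1.19 and 1.48 for 95% of them, a range not centred on 0, and 302 of the 10778 pairs lay above it and 457 below. With no test possible, the pairs named here were taken by the size of their difference among the genes that the ranking kept, and wider pairs lay outside it. The widest with exon 5 higher were at Rpl23a, a ribosomal protein gene (1.90 with exon 5, chromosome 11, 78181236 to 78181285, against -2.18 without, 78181186 to 78181385), and Atp5b, an ATP synthase subunit gene (5.22, chromosome 10, 128085801 to 128086000, against 1.68, 128085851 to 128086200), in the authors' deposited tables. Here and at other pairs the clusters differ in extent, so the 2 values of a pair need not cover the same stretch. Pcm1 (3.77 against 0.48), Btaf1 (3.51 against 0.41), Eif3c (2.64 against -0.12), Rbm26 (4.78 against 2.14) and Rps19 (4.03 against 1.40) were also among the widest in the authors' deposited tables, together with a glycine and an arginine tRNA gene. With exon 5 lower, the widest of these were at Zc3h14, which encodes a poly(A)-binding zinc finger protein (-0.15 with exon 5 against 3.03 without, chromosome 12, 98757151 to 98757200), and Pcbp3 (0.88 against 4.03, chromosome 10, 76892586 to 76892685), in the authors' deposited tables. Atp6v0a1 (1.11 against 4.12), Dazap2 (-0.97 against 1.92), Snhg1 (-1.37 against 1.47), Mphosph8 (-0.59 against 2.24), Ywhae (-1.16 against 1.39), Lmbrd2 (-0.44 against 2.06), Psd (1.62 against 4.05) and Mki67 (-1.22 against 1.17) completed this direction in the authors' deposited tables. Whether any of these exceeds the spread between replicates, or follows isoform or induction time, is unknown.

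A further comparison asks whether the Puf60 isoforms share sites with each other more than with Rbm38. For enriched clusters lying in a single gene, 63.1% of those with exon 5 overlapped an enriched cluster without exon 5, and 21.1% overlapped an enriched cluster of Rbm38. After moving each cluster to a random place in its gene, the mean shares over 100 draws were 5.30% and 4.80%. For Puf60 without exon 5, 19.2% overlapped an enriched cluster of Rbm38, against 4.62% after the moves. Every draw gave a lower share than observed for these 3 pairs (one-sided permutation p = 0.0099, the smallest that 100 draws allow). The moves spread clusters evenly over the gene body, but the listed clusters were not spread evenly. The last of 10 equal parts held 17.3% of enriched clusters with exon 5 and 47.8% of those of Rbm38. Reads that cover the same parts of a gene could thus also exceed the moves, which cannot separate this from shared binding. Over all listed clusters, the comparison fixed before the data were examined, 58.1% of clusters with exon 5 overlapped one without exon 5, 44.7% overlapped one of Rbm38, and 44.1% of those without exon 5 overlapped one of Rbm38. In the more strongly enriched 50% of clusters the shares with Rbm38 fell to 24.3% and 21.6%, and among enriched clusters in single genes to 10.3% and 8.44%, above random moves in each case. This cut was made by deposited p-value in both tables, so fewer Rbm38 clusters were left to overlap. For enriched clusters the shares after random moves fell as well, to 2.95% and 2.69%. Overlap between the isoforms did not fall, at 61.8% of all clusters with exon 5. Whether stronger sites are shared less with Rbm38 was not tested apart from this. Where a cluster was listed in both a Puf60 and the Rbm38 table, enrichment in one did not go with enrichment in the other. The odds ratio was 0.882 over 14851 matched pairs with exon 5 (p = 0.000258, two-sided Fisher's exact test) and 0.645 over 16078 pairs without exon 5 (p = 4.08e-38). The corresponding Pearson r of the log2 folds was 0.0814 and -0.00577, across clusters. With an overlap of 50% of both clusters required, the odds ratio with exon 5 was 0.982 (p = 0.641, Fisher's exact test) and no longer passed the threshold.

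**Figure D2:**
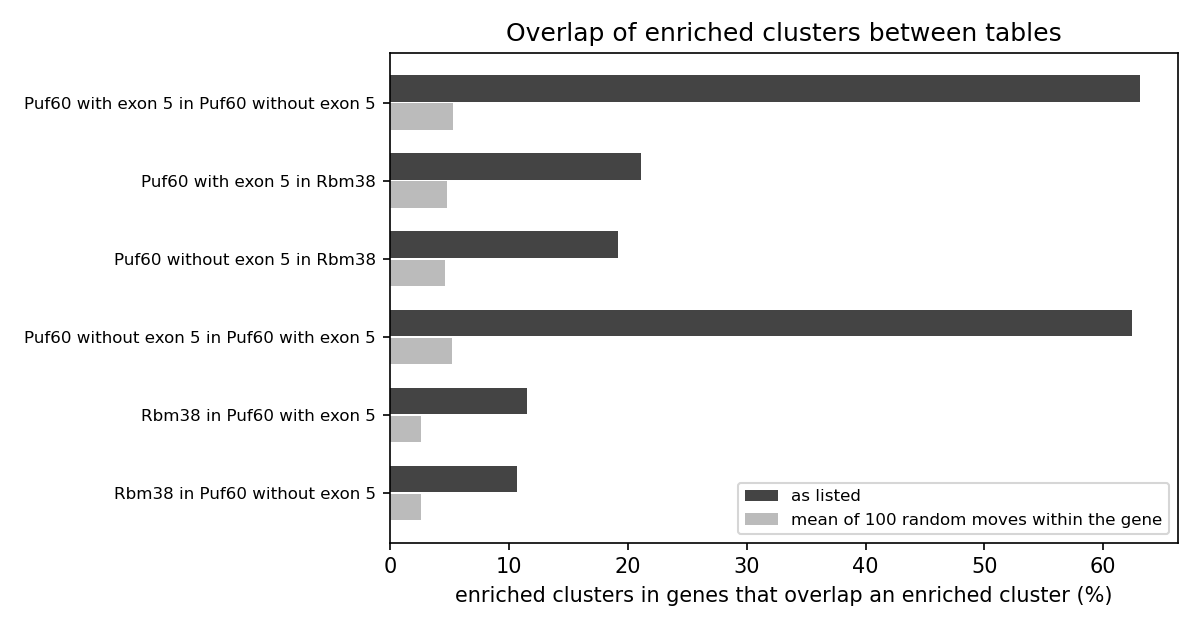
Share of enriched clusters in single genes (x axis, percent) that overlap an enriched cluster of another table on the same strand, for each ordered pair of tables; dark bars show the clusters as listed and light bars the mean of 100 random moves within the gene. Puf60 with exon 5 overlaps Puf60 without exon 5 at 63.1% and Rbm38 at 21.1%.

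By gene, 3497 of the 4269 genes with an enriched cluster of Puf60 with exon 5 also had one without exon 5 (81.9%, 80.7 to 83.0), an odds ratio of 28.8 among the 9737 genes listed in any table. Of the same 4269 genes, 2869 were shared with Rbm38 (67.2%, 65.8 to 68.6), an odds ratio of 1.44, and 2843 of the 4240 genes without exon 5 were (67.1%, 65.6 to 68.5), an odds ratio of 1.42. Independent sets of these sizes would share 1859, 2665 and 2647 genes. These odds ratios depend on the setting, at 69.8, 6.27 and 5.92 with at least 2 enriched clusters per gene and 127, 12.4 and 12.2 against all protein-coding genes. Over all listed clusters, the odds ratios with Rbm38 were 0.851 (adjusted p = 0.00432) and 0.827 (adjusted p = 0.00166, two-sided Fisher's exact test adjusted over 3 pairs). These 2 values reversed under each of the 3 alternatives tried, and a gene in neither compared table entered the background only through the third table.

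Most clusters lay in protein-coding genes. The share among enriched clusters was 79.2% (78.5 to 79.8) for Puf60 with exon 5, 79.9% (79.2 to 80.5) without exon 5 and 82.1% (81.6 to 82.5) for Rbm38. Genes of long noncoding RNA held 3.11%, 3.04% and 2.13%, and 10.7%, 10.3% and 8.17% lay outside genes. The isoforms did not differ in the protein-coding share by Fisher's exact test (odds ratio 0.957, adjusted p = 0.134), and each was lower than Rbm38 (odds ratios 0.831 and 0.869, adjusted p = 9.61e-12 and 2.16e-07). Exons, introns and untranslated regions were not analysed here.

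Along protein-coding genes, Rbm38 and Puf60 differed at the 3′ end. Within 2000 nt of the annotated 3′ end lay 41.3% (40.6 to 42.1) of the enriched Rbm38 clusters and 9.49% (9.05 to 9.94) of those not enriched, an odds ratio of 6.72. For Puf60 with exon 5 the shares were 14.7% (14.0 to 15.4) of enriched and 29.6% (28.9 to 30.4) of other clusters, an odds ratio of 0.408, and without exon 5 they were 14.5% and 33.6%, an odds ratio of 0.335. All 3 odds ratios passed the two-sided Fisher's exact test (adjusted p = 0 at machine precision, 1.27e-167 and 8.46e-274). At the 5′ end, the share of enriched clusters was lower than that of other clusters for Rbm38 (5.04% against 8.14%, odds ratio 0.599, adjusted p = 4.74e-31), and neither Puf60 table passed the test (adjusted p = 0.219 with exon 5 and 0.426 without). This measurement was added after the data were examined and used the protein-coding genes among the 5194 whose strand the clusters gave.

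**Figure D3:**
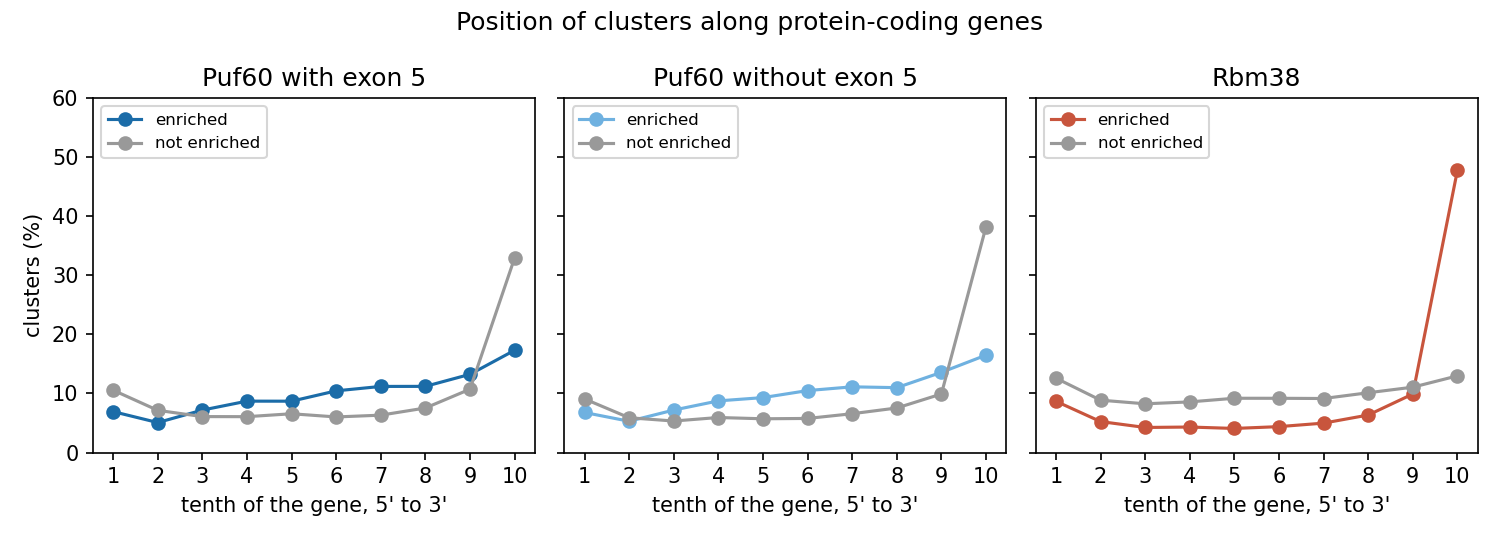
Percent of clusters (y axis) in each of 10 equal parts of the protein-coding gene from 5′ to 3′ (x axis), for enriched clusters (coloured) and other clusters (grey) of each table. The part at the 3′ end holds 47.8% of the enriched Rbm38 clusters, against 17.3% for Puf60 with exon 5 and 16.5% without exon 5.

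Among the 11 gene lists fixed before the data were examined, splicing factors had the highest odds ratio for both Puf60 isoforms, and the smallest p for all 3 proteins by Fisher's exact test. With gene length in a logistic regression, ribosomal protein genes had the smallest p for each protein. Both tests counted only list members with a cluster in any table, and the other members were left out. The members counted included 64 of 67 splicing factors, 29 of 52 neurogenesis regulators, and 11, 5 and 7 of 15 neuron, glia and progenitor markers. An enriched cluster was found in 60 of the 64 listed splicing factors with exon 5 (93.8% against 43.5% of other genes, odds ratio 19.5, adjusted p = 1.94e-16), in 60 without exon 5 (odds ratio 19.7, adjusted p = 1.31e-16) and in 61 for Rbm38 (odds ratio 12.3, adjusted p = 1.03e-08, Fisher's exact test, adjusted over the list of 11). U2af2, the large subunit of the pyrimidine tract-binding factor, had log2 folds of 6.01 with exon 5 and 6.08 without in the authors' deposited tables, at overlapping clusters that start at 5069201 and 5068801 on chromosome 7. Srsf11, an SR protein gene, had 5.46 and 5.26, and Ptbp2, a neuronal splicing repressor gene, had 4.85 with exon 5, in the authors' deposited tables. For Rbm38, members with the smallest p included Celf1 (5.31), Hnrnpk (5.02) and U2af1 (4.87) in the authors' deposited table, with cluster centres 197, 229 and 80 nt from the 3′ end of the gene.

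Ribosomal protein genes carried an enriched cluster in 48 of 71 with exon 5 (odds ratio 2.69, adjusted p = 0.000218), 56 without exon 5 (odds ratio 4.89, adjusted p = 9.14e-09) and 63 for Rbm38 (odds ratio 4.78, adjusted p = 4.87e-06). With gene length in the model these odds ratios were 4.48, 8.59 and 7.18. Rpl10a led for the Puf60 isoforms with log2 folds of 4.56 and 4.23, and Rps24 (6.65), Rpl32 (4.92) and Rpl27 (4.80) for Rbm38, in the authors' deposited tables. Genes of this family have many processed copies, so reads may be shared between them. Cytoskeleton and trafficking genes carried one in 31, 30 and 34 of 38 (odds ratios 5.71, 4.89 and 5.14). Examples in the authors' deposited tables are Kif1b, a kinesin gene (6.55 and 5.17 for Puf60 with and without exon 5), Agap1 (5.97 and 6.99) and, for Rbm38, Ank2 (5.89) and Cltc, the clathrin heavy chain gene (5.18). The clusters gave no strand for Ank2, so its cluster may be antisense to the gene. Chromatin regulators carried one in 29, 33 and 34 of 40 (odds ratios 3.39, 6.15 and 3.42), among them Kmt2d (3.52 with exon 5) and Atrx (5.60 and 5.93) for Puf60 and Dnmt1 (6.33) and Hdac2 (4.96) for Rbm38 in the authors' deposited tables. With gene length in a logistic regression, the call of the cytoskeleton list (odds ratio 3.36, adjusted p = 0.0559) and that of the chromatin list (2.42, adjusted p = 0.0927) were lost for Rbm38.

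Of the lists tied to neurons, neurogenesis regulators carried an enriched cluster in 19, 19 and 23 of 29 genes for Puf60 with exon 5, without exon 5 and Rbm38 (odds ratios 2.44, 2.47 and 2.31; adjusted p = 0.0430, 0.0421 and 0.10). Axon guidance and synapse genes carried one in 33, 29 and 34 of 47 (3.03, 2.10 and 1.58; adjusted p = 0.000715, 0.0381 and 0.194). With gene length in the model, no call of these lists for Puf60 held. The odds ratios of neurogenesis regulators moved little, to 2.27 and 2.29 (adjusted p = 0.0902 and 0.0859), and those of axon guidance and synapse genes fell to 1.68 and 1.10 (adjusted p = 0.172 and 0.790). Insm1, a neuroendocrine transcription factor gene, had 4.84 and 4.56 for the Puf60 isoforms in the authors' deposited tables, and Hand2, a sympathetic neuron transcription factor gene, had 3.35 and 3.16. Snap25, a synaptic vesicle fusion gene, had 5.50 and 6.04, and the glutamate receptor gene Gria2 had 5.35 and 6.55 with and without exon 5 in the authors' deposited tables. For Rbm38, Mapt (6.43), Nfia (5.29), Gap43, a growth cone protein gene (5.10), and Stmn1, a microtubule regulator gene (4.60), led the neurogenesis list in the authors' deposited table. The clusters gave no strand for Nfia, so its cluster may be antisense to the gene. Neuron markers carried one in 11 of 11 for Rbm38 (odds ratio 13.9 with 0.5 added to each cell, adjusted p = 0.0168) and 8 of 11 for each Puf60 isoform (adjusted p = 0.0944 and 0.106). Glia markers carried one in 2, 2 and 1 of 5, and progenitor markers in 6, 5 and 6 of 7, with no call for either list. The odds ratio of neuron markers for Rbm38 lay above that of splicing factors here, and below it with at least 2 clusters (4.93 against 18.1) and against all protein-coding genes (8.05 against 30.0).

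The p53 and cell cycle list passed the test for Rbm38, with 26 of 30 genes (odds ratio 3.92, adjusted p = 0.0155), and not for Puf60, with 16 genes with exon 5 and 17 without (adjusted p = 0.437 and 0.269). The list's split between Rbm38 alone (10 genes) and Puf60 alone (3 genes) was not distinguishable from that of other genes (odds ratio 2.07, adjusted p = 0.864), so a difference between the proteins was not shown. Ccnb1 (4.43), Cdk1 (4.23), E2f1 (4.43) and Ccna2 (4.03), all genes of cell division, led this list for Rbm38 in the authors' deposited table. Abundant nuclear noncoding RNAs did not stand above other genes for any protein (6, 7 and 5 of 14; adjusted p = 1, 0.867 and 0.0813). Malat1, a nuclear RNA of speckles, had log2 folds of 2.56, 2.56 and 1.87 in the authors' deposited tables. None of these tests accounts for expression level, which was not analysed here.

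**Figure D4:**
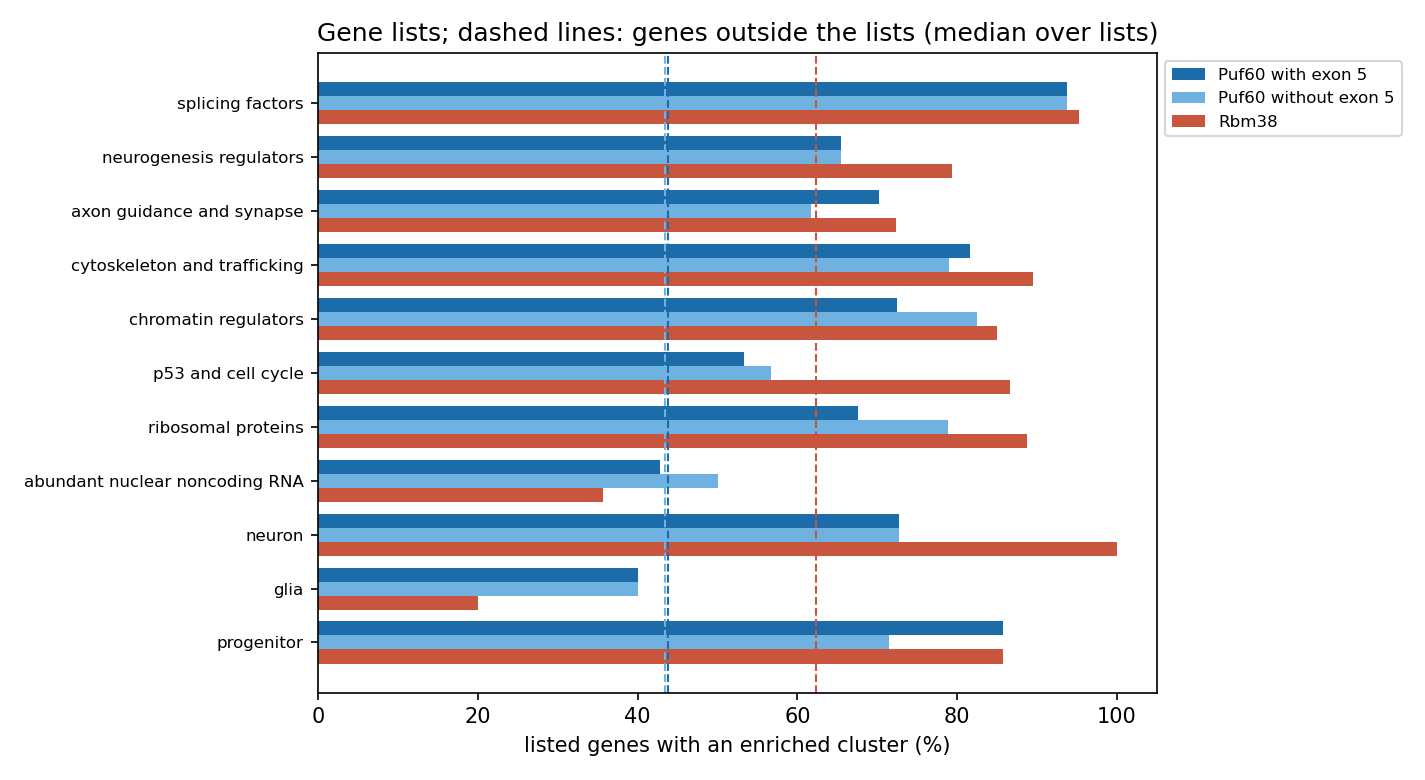
Percent of list genes with a cluster in any table that hold an enriched cluster (x axis), for each of 11 lists, by protein (bars). Dashed lines give the share among genes outside the list, as the median over lists. Splicing factors reach 93.8%, 93.8% and 95.3% for Puf60 with exon 5, without exon 5 and Rbm38.

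Clusters in genes of small RNAs mostly lay below input. Small nucleolar RNA clusters had a median log2 fold of -2.72 with exon 5, -2.89 without and -3.17 for Rbm38 in the authors' deposited tables, and 4 of 245, 3 of 250 and 0 of 264 were enriched. Clusters on the mitochondrial genome had medians of -2.49, -2.58 and -1.08 in the authors' deposited tables, with 0 of 19, 0 of 24 and 0 of 26 enriched. Spliceosomal and other small nuclear RNA clusters had medians of -0.42, -0.76 and -1.10 in the authors' deposited tables, and 12 of 180, 14 of 187 and 3 of 129 were enriched. Of ribosomal RNA clusters, 1 of 21, 0 of 19 and 0 of 22 were enriched. The few microRNA clusters lay nearer to input, with medians of 0.17, -0.22 and 0.0083 in the authors' deposited tables, and 6 of 15, 5 of 17 and 5 of 18 were enriched. Transfer RNA clusters had medians below input too, at -0.81, -1.90 and -0.64 in the authors' deposited tables. Enrichment was found at 58 of 232 (25%, 19.9 to 30.9) for Puf60 with exon 5, 3 of 249 (1.2%, 0.411 to 3.48) without exon 5 and 42 of 168 (25%, 19.1 to 32.1) for Rbm38. The odds ratio between the isoforms was 27.3 (adjusted p = 2.64e-16, two-sided Fisher's exact test adjusted over 5 classes), and none of the other 4 classes (small nucleolar, small nuclear, ribosomal and microRNA) passed the test (adjusted p = 1 in each). At 228 matched tRNA clusters the median log2 fold with exon 5 was 1.35 above that without, and 217 were higher with exon 5. Fisher's test took the tables as separate sets although these 228 clusters were listed in both, and no paired test was made. Copies of tRNA and small nuclear RNA genes are near-identical, so reads may be shared between loci, and isoform and induction time are confounded here as well.

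**Figure D5:**
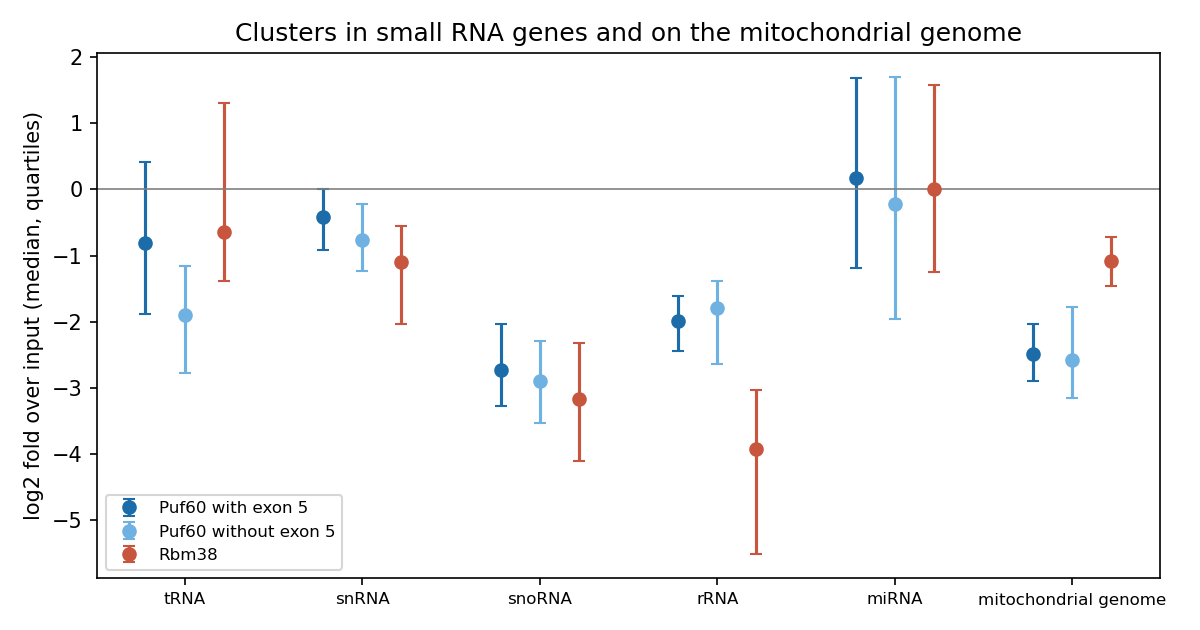
Median log2 fold over input, with quartiles as bars (y axis), of clusters in small RNA genes and on the mitochondrial genome (x axis), by protein, as the authors' deposited tables give them. The tRNA median is -0.81 with exon 5, -1.90 without exon 5 and -0.64 for Rbm38.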

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

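The tests in this part were chosen after the patterns were seen, except that of the protein-coding share among all clusters, which was fixed before the data were examined. Each result below differed between proteins by a test of the difference, over clusters and not over replicates.

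Clusters in tRNA genes were enriched more often for Puf60 with exon 5 than without, with an odds ratio of 27.3. A shift common to all small RNAs and as large as that of tRNA is argued against. Matched snoRNA clusters differed by a median of 0.171 in log2 fold (bootstrap interval 0.115 to 0.255), against 1.35 (1.21 to 1.47) for tRNA. The medians were 0.277 for 163 small nuclear RNA, 0.348 for 10 microRNA and -0.262 for 15 ribosomal RNA clusters, without intervals. Outside small RNA genes the median was 0.090, so a smaller shift shared by some classes stays open. These values do not address a difference limited to tRNA, in size selection or in either input. Such a difference was not tested. For the difference in log2 fold, a few tRNA sequences counted at many gene copies are argued against too. The median difference was above 0 in 20 of 20 amino acid families, from 0.55 to 2.30. For the odds ratio this stays open, since the 58 enriched clusters with exon 5 were spread less evenly. Arginine tRNA held 12, serine 9, threonine 9 and lysine 7 of them, while isoleucine, methionine, valine and tyrosine tRNA held 0. Longer induction of the line with exon 5 cannot be told apart from the isoform, which the design names, because no library of that isoform's CLIP was induced for 24 h. The Rbm38 table, at 24 h, held 42 enriched tRNA clusters, so a long induction is not needed for tRNA enrichment in general, but Rbm38 is another protein and this leaves the question open.

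The concentration of enriched Rbm38 clusters at gene 3′ ends exceeded that of Puf60, with ratios of odds ratios of 16.5 (15.1 to 18) against Puf60 with exon 5 and 20.1 (18.4 to 21.9) against Puf60 without it. Tables that list clusters at different places are argued against as the whole cause: over clusters listed in both the Rbm38 table and that of Puf60 with exon 5, the odds ratio of Rbm38 enrichment at 3′ ends was 4.72, and that of Puf60 was 0.434. Short genes that lie within the window are argued against, since genes over 20000 nt gave 10.1 for Rbm38. Binding of Rbm38 near mRNA 3′ ends remains a hypothesis, found and tested on the same data, and the RNA make-up of the inputs was not tested.

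The 3′ end odds ratio of Puf60 without exon 5 was 0.821 times that with exon 5 (95% interval 0.748 to 0.900). The shares of enriched clusters were close, at 14.5% without exon 5 and 14.7% with it. The difference lay in the clusters not enriched, at 33.6% and 29.6%, and so need not mark a difference in enriched sites. The odds of lying in a protein-coding gene were lower for Puf60 than for Rbm38 among all clusters (odds ratios 0.865 with exon 5 and 0.882 without) and among enriched clusters (0.831 and 0.869).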

How the results depend on the processing

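The versions of the cluster overlap between proteins, target gene overlap and regions restricted to enriched clusters, the added adjustment, the minimum log2 fold of 1 and the 3′ end windows were chosen after seeing the data. Of the recomputed values, 128 stayed on their side of the threshold, within their error or, for counts of enriched clusters, within 1.5 times the main count. A threshold of 0.01 left 13745, 13634 and 24556 enriched clusters for Puf60 with exon 5, Puf60 without exon 5 and Rbm38, adjusting all deposited p-values gave 15540, 15437 and 30358, and a log2 fold of at least 1 left 12646, 12478 and 22718. The cluster overlaps kept their direction against random moves under 50% overlap, the more strongly enriched 50% and either strand. The 3′ end results kept theirs under each window and in long genes. The share overlapping Rbm38 was lower in the more strongly enriched 50%, from 22.2% to 11.5% with exon 5 and from 20.0% to 9.77% without among all enriched clusters. That cut was made in both tables, which left fewer Rbm38 clusters to overlap. Among the more strongly enriched 50%, the protein-coding share moved to 78.8%, 79.5% and 81.7% of all clusters and to 77.1%, 77.7% and 83.4% of enriched clusters, in the same order of proteins. Pairs overlapping by 50% had a Pearson r of 0.946. The target gene odds ratio with Rbm38 over all clusters reversed for Puf60 with exon 5, to 11 with at least 2 clusters, 1.58 in the more strongly enriched 50% and 29.7 against all protein-coding genes, and for Puf60 without exon 5, to 11.3, 1.58 and 32.9. Genes in neither compared table enter the main background only through the third table, which lowers the main value by construction. With gene length as a covariate, the odds ratio of neurogenesis regulators was 2.27 with exon 5 and 2.29 without, that of axon guidance and synapse genes 1.68 and 1.10, and for Rbm38 that of cytoskeleton genes 3.36 and of chromatin regulators 2.42, none past the threshold. Other calls kept their side while their odds ratios moved: splicing factors had 34.8, 28.7 and 18.1 with at least 2 clusters and 40.8, 40.6 and 30.0 against all protein-coding genes, for Puf60 with exon 5, Puf60 without exon 5 and Rbm38, and in the same order cytoskeleton genes had 4.65, 4.96 and 8.25, then 10.5, 9.39 and 9.09, and chromatin regulators 6.29, 6.03 and 2.51, then 8.05, 11.9 and 8.33. Ribosomal protein genes had 5.14, 4.15 and 3.65, then 9.89, 17.7 and 23.3. Axon guidance and synapse genes had 3.10 and 2.06 for Puf60 with and without exon 5, then 6.77 and 5.04. The cause of the other changes was not tested. New calls with at least 2 clusters were neurogenesis (3.03) and axon guidance (1.93) for Rbm38, p53 and cell cycle (2.78) and neuron markers (4.99) with exon 5, and neuron (10.7) and progenitor markers (5.32) without. Against all protein-coding genes they were neurogenesis (2.32) and axon guidance (4.54) for Rbm38, p53 and cell cycle (3.27 and 3.62) and neuron markers (5.36 and 5.34) with and without exon 5, and progenitor markers with exon 5 (3.13).

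Logistic regression could not be fitted for the neuron list of Rbm38, where 11 of 11 genes had an enriched cluster. Other normalizations, DESeq2 or no low-count filter, pseudocounts, pooled inputs, the difference of CLIP over input ratios, leaving out replicates, intron priority, and the motif and splice site alternatives were not run, since the tables give no values per library and no sequence or exons were used here. No paired analysis was possible because the tables carry no columns per replicate. Depth is unknown, so a cluster missing from a table does not show that the RNA was unbound.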

Other observations

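The tests in this part were chosen after the data were examined; the one that leaves out genes with many clusters had its prediction written before its result was seen.

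Families of tRNA were compared by value between Rbm38 and Puf60 with exon 5. Rbm38 had 13 of 20 alanine tRNA clusters enriched, with a median log2 fold of 1.44, and Puf60 with exon 5 had 5 of 21, with a median of -0.73, in the authors' deposited tables. Asparagine tRNA clusters had medians of 2.71 for Rbm38 and -1.67 for Puf60 with exon 5, and arginine tRNA clusters of -1.39 and 0.23, in the authors' deposited tables. For asparagine, 3 of 7 clusters were enriched for Rbm38 and 2 of 7 for Puf60 with exon 5. For arginine, 3 of 17 and 12 of 24 were. Threonine and serine tRNA clusters had medians above 0 in both, at 1.04 and 0.90 and at 0.56 and 0.68, in the authors' deposited tables. Differences between families were not tested.

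Some chromosomes held more clusters in 1 Puf60 table than in the other. Chromosome 10 had 3180 listed clusters with exon 5 and 2661 without, and chromosome 1 had 2112 and 2933. Over 20 chromosomes, the log2 ratio of cluster numbers of enriched clusters followed that of clusters not enriched, with a Pearson r of 0.829 (permutation p = 5e-05), a Spearman rho of 0.684 (permutation p = 0.00111) and an r of 0.642 without the chromosomes farthest from the median, 1 and 10. A shift of binding on some chromosomes stays open. Clusters that were not enriched also split unevenly (chi-square 153.5, p = 4.53e-23, although clusters are not independent), which counts against it, but the median difference of matched log2 folds rose with the ratio of listed clusters (Pearson r 0.512, permutation p = 0.0200, adjusted over 2 relations p = 0.0200; Spearman rho 0.474, permutation p = 0.0357; r of 0.463 without chromosomes 1 and 10), which goes with it. A few genes with many clusters are argued against as the whole cause, since r was 0.819 (permutation p = 3e-05) without the 309 genes that hold 20 or more. They account for part of it on chromosome 10, where Pcbp3 alone held 391 and 236 clusters: without such genes the log2 ratio of listed clusters there fell from 0.26 to 0.12, and that of chromosome 1 went from -0.47 to -0.41. More RNA from some chromosomes in one line, by copy number or expression, may account for it and stays open along with induction time, so that clusters listed for a single isoform need not mark a difference in binding.

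Among clusters whose p-value was under 0.01, the share with an adjusted p of 1 fell with the log2 fold. For Rbm38 it was 2177 of 4182 such clusters (52.1%) with a log2 fold from 0 to 1, 2106 of 8989 (23.4%) from 1 to 2 and 195 of 16030 (1.22%) above 2, in the authors' deposited table.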
